A study of Mus musculus with 20 samples.

How the data were processed

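Omni-ATAC-seq, an assay in which a transposase inserts sequencing adapters into accessible DNA, was carried out on E14Tg2a mouse embryonic stem cells and clones derived from them. In the parental degron line the endogenous CTCF protein is removed by indole-3-acetic acid, an auxin, while doxycycline switches on a Ctcf transgene. CTCF is a zinc finger protein that binds DNA and, with cohesin, shapes chromatin loops. The 20 samples make 10 genotypes with 2 replicates each: a wild-type transgene (WT) and 9 transgenes with a single amino acid substitution in or next to the zinc fingers. The zinc finger of each residue, on which the grouping of mutants by part of the protein rests, comes from general knowledge of CTCF and not from the labels. Per the labels' protocols, all samples were treated with 500 µM indole-3-acetic acid and 1 µg/ml doxycycline for 2 days, 50000 cells entered each reaction, and about 50 M paired-end reads of 150 bp were planned per sample. Whether the 2 replicates came from separate cultures is not given in the sources used here.

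The submitters' processing notes name Trim Galore, Bowtie2, MACS2 and deepTools and the mouse build mm10, without versions. Adapter shifting, duplicate handling and the calling threshold are not given in the sources used here. The authors deposited 1 peak list per genotype, and each peak name in these lists carries 2 library codes, so both replicates entered each list. No list per replicate was analysed here, so no spread between replicates could be measured and no test between genotypes was possible. All intervals given are exact binomial or bootstrap 95% intervals, or ranges of simulated draws. The binomial intervals and the draws cover counting error over peaks only. The bootstrap drew whole chromosomes, so its intervals cover the spread between chromosomes, and none of the intervals holds a spread between replicates. The deposited lists hold a position, a peak name and 1 value per peak, without a header. The authors called peaks with MACS2 before the lists were deposited, per the submitters' processing notes, and the deposited value is read from its range and steps as the fold enrichment of MACS2, a ratio of coverage at the peak to expected coverage. It is the authors' own value and was used only to describe, rank or filter peaks within a list. Peak numbers within each deposited list skip 1.29% to 1.44% of the series, and the reason is not given in the sources used here.

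Read totals were not used here. Relative depth was taken from the values instead. In each list 28.9% to 33.8% of the fold values lay, within 1.1e-05, on whole multiples of a step, against at most 0.0185% on a grid offset by 50% of that step. With whole read pileups p and an expected background coverage c, a fold of (p + 1)/(c + 1) gives such a step, so c was computed as 1/step minus 1 and called the background coverage. It ran from 3.49 in the K365T list to 5.96 in the WT list. In 8 lists the 2 library codes were consecutive. In the WT and K365T lists they lay 28 and 42 numbers apart, which could mark another library batch that is tied to those genotypes and cannot be separated from them.

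A peak counted as found in another list when at least 1 bp overlapped. Each WT peak was placed in 1 of 20 bins of equal size by its fold value, and comparisons at equal strength were standardised over these bins. Mutant peaks without a WT overlap were called gained. Peaks were located with a RefSeq gene table of GRCm38.p6, which has the same chromosomes as mm10, holds 49939 genes on them, 21883 of them protein-coding, and gives gene starts and ends without strand or exons. The class planned as promoters was therefore replaced by peaks within 1 kb of either annotated end of a protein-coding gene, called gene-end peaks. Other peaks inside such a gene were called gene-body peaks, and the rest intergenic. Coordinates are 1-based mm10 positions. Without a genome sequence, the planned comparisons that rest on the CTCF motif (retention of motif peaks, motif share of each list, retention by motif position, and list size against motif retention) were not run. The expected number of WT peaks missing from several lists came from 1000 simulations in which each list loses peaks independently at its own share per strength bin. Gene lists were compared with 10000 random lists matched on the strength decile of the WT gene-end peak. Copy-number-like shifts were searched in 5 Mb bins holding a median of at least 50 peaks. A run of 3 or more bins more than 0.2 (log2) from the median of the other lists, on the same side, was called a shifted segment. Runs of missing WT peaks were searched among the stronger 60% of WT peaks, with weaker peaks left out. Correlations over lists were tested two-sided by permuting pairings, exactly for 9 lists and with 100000 draws for 10 lists, with Benjamini-Hochberg adjustment over 5 relations.

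The groups, the comparisons of lists, locations, gene lists and mutant pairs, the naming rule and most alternatives were fixed before the data were examined. For locations the plan held only the share of each class among shared, missing and gained peaks. The gene-end minus intergenic difference at equal strength, with its bootstrap interval, was not in the plan. The comparisons of chromosome shares and segments, the relations of depth or list size to the share of WT peaks found, and those of the Meg3 to Mirg interval and other gene clusters were chosen after the data were seen. Named peaks were the 10 WT peaks with the highest fold among those in no mutant list, the 10 regions with the best median rank among those in all 9 mutant lists and not in WT, and per mutant the 2 strongest WT peaks missing from that list alone and the 2 strongest peaks found in that list alone, of which the text gives a part. A few items that the naming rules select are not reported here. Genes of the fixed lists were named where presence of a gene-end peak differed between WT and a mutant, at most 4 per list. The imprinted list is an exception, with all 5 genes that had a WT gene-end peak missing in a mutant named. Hoxd11 and Pcdhb11, missing in all 9 mutants, were also named although the planned order by WT fold does not select them. Alternatives were an overlap of at least 50% of the tested peak, the stronger 50% of each list as the peaks looked for, every list limited to its 121032 strongest peaks (the size of the smallest list), windows of 0.5 and 2.5 kb around gene ends, and other reference lists. Leaving out the chromosomes that hold shifted segments was added after the data were seen. Scripts ran on Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap code was checked against bedtools 2.31.1, with a difference of 0 among the 171719 WT peaks at 1 bp. For the 50% overlap the counts differed by 1599 peaks, since cover was summed over all peaks of the other list here and bedtools takes single peaks. On simulated losses a true difference of 5 percentage points between classes came back as 5.03 on average.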

Results

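Accessible chromatin was mapped in mouse embryonic stem cells whose own CTCF had been removed and replaced by a WT or a mutant transgene, with 2 replicates per genotype combined by the authors into 1 peak list. The mutants were R339Q and R342C in the third zinc finger, S354F and K365T in the fourth, R377C and R377H in the linker between the fourth and the fifth, Q418R in the sixth, and R448Q and H455R in the seventh. The comparison asks which accessible regions differ when the only CTCF in the cell carries a given substitution. The WT list held 171719 peaks over 86.1 Mb. Mutant lists ranged from 121032 peaks over 61.4 Mb in R339Q to 159957 peaks over 79.2 Mb in H455R, with median peak widths of 385 to 426 bp. Background coverage, the measure of depth that the values allow, was 5.96 for WT, 5.45 for R448Q and 3.49 to 4.66 for the other mutants. No value below has a replicate error. The intervals cover counting error only or, where from the bootstrap, the spread between chromosomes.

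Ctcf itself, on chromosome 8 from 105636474 to 105682922, carried a peak at an annotated end in all 10 lists. That peak stood between the 77.2nd percentile of the Q418R list and the 86.7th percentile of the H455R list. The number of peaks in the gene ran from 3 in R339Q to 11 in R377C and H455R, against 10 in WT. The lists do not separate the endogenous gene from the transgene.

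Most strong accessible sites of WT cells were present in every mutant. Of the 34343 WT peaks in the strongest 20%, 97.6% were found in all 9 mutant lists, and over all WT peaks 83262 (48.5%) were. The strongest WT sites were missing most often in R339Q, with 331 peaks (0.964%, 95% interval 0.863 to 1.07), and in R448Q, with 306 peaks (0.891%, 0.794 to 0.996). On chromosomes without shifted segments the order was the other way, with 1.08% in R448Q and 0.956% in R339Q. Q418R lacked 140 of the strongest sites (0.408%, and 0.276% on those chromosomes), K365T 104, R377H 95, R342C 76, S354F 74, H455R 41 and R377C 39. Losses concentrated among weak sites: of the weakest 20% of WT peaks, 46.5% were missing in H455R and 69.5% in R339Q. Across all WT peaks, the share found was lowest for R339Q (64.9%) and Q418R (69.2%) and highest for R377C (79.1%) and H455R (80.7%). K365T stood at 71.7%, R448Q at 72.3%, R342C at 73.9%, R377H at 74.0% and S354F at 75.7%; the exact (Clopper-Pearson) 95% interval was 64.7 to 65.1% for R339Q and 80.5 to 80.8% for H455R. When every list was limited to its 121032 strongest peaks, R339Q (78.4%) and R448Q (78.6%) were lowest and S354F (84.0%) and R377C (84.4%) highest.

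**Figure D1:**
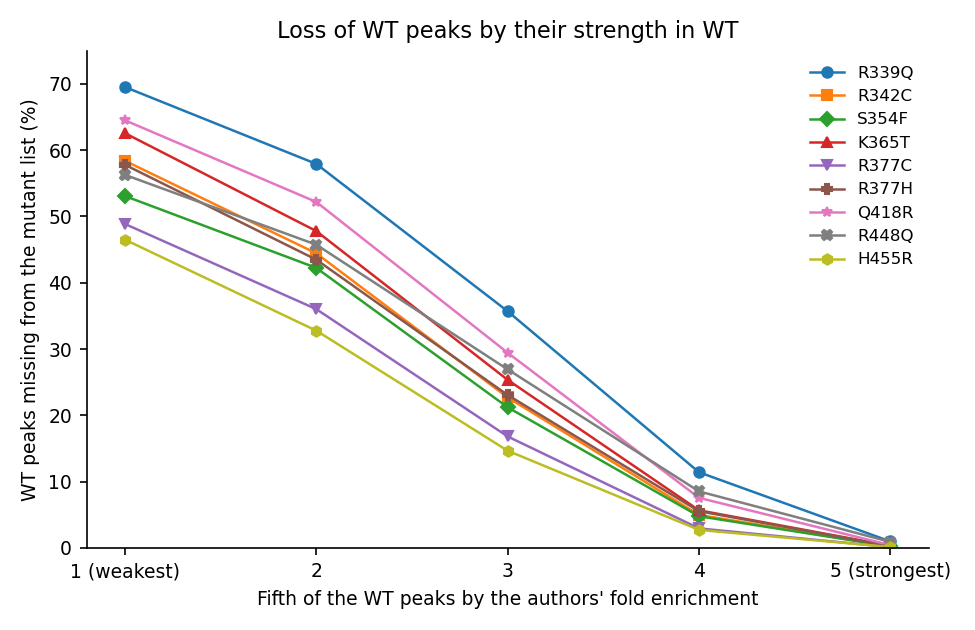
Share of WT peaks with no overlapping peak in each mutant list (vertical axis, percent) by class of 20% of the WT list ordered by the authors' fold enrichment (horizontal axis), 1 line per mutant. Every line descends, from 46.5 to 69.5% in the weakest class to under 1% in the strongest, and R339Q lies on top in all of them.

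The strongest WT sites missing from a single mutant lay mostly away from gene ends. R448Q alone lacked an intergenic peak 361 kb from Adamts9, a metalloprotease gene, on chromosome 6 (93305090 to 93305738, fold 17.6). In R339Q they were inside Dkk2, which encodes a secreted modulator of Wnt signalling, on chromosome 3 (132154868 to 132155519, fold 15.5) and inside Stard13 on chromosome 5 (151141539 to 151142206, fold 14.7). Q418R alone lacked peaks inside Medag on chromosome 5 (149424018 to 149424382) and inside Lyn, a Src-family kinase gene, on chromosome 4 (3734570 to 3734883). R377H alone lacked a peak inside the histone acetyltransferase gene Kat6a on chromosome 8 (22866320 to 22866819), and R377C one 50.2 kb from Herc3 on chromosome 6 (58780634 to 58781275). R342C alone lacked a peak inside Rasgef1c on chromosome 11 (49928328 to 49928776), S354F one 34.7 kb from Srek1 on chromosome 13 (103703423 to 103703851), K365T one 25.5 kb from Pfkp on chromosome 13 (6674552 to 6675431), and H455R one inside Spink13 on chromosome 18 (62685397 to 62685748). The number of WT peaks missing from 1 list alone was 3889 in R339Q, 3558 in Q418R, 2036 in K365T and 2016 in R448Q, and 274 to 933 in the other 5 mutants.

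WT peaks with no counterpart in any mutant numbered 9310 (5.42% of the WT list), none above the 79.8th percentile of WT strength. The strongest lay on chromosome 7 in the noncoding gene C230079O03Rik (136333363 to 136333672, fold 8.33) and inside Pds5b, which encodes a cohesin-associated protein, on chromosome 5 (150751411 to 150751721, fold 7.90). Others lay inside Klhl13 on chromosome X (23299221 to 23299596), inside Slc35a1 on chromosome 4 (34671126 to 34671376), inside Stard13 on chromosome 5 (151089206 to 151089505), at a gene end of Pnma3 on chromosome X (73068166 to 73068471) and inside Cbx5, the gene of heterochromatin protein HP1 alpha, on chromosome 15 (103202195 to 103202744). Independent losses at equal strength would leave 290 such peaks (simulated 95% range 254 to 324). All comparisons share the WT list, and weak sites differ in how easily they are called. With a mutant as the reference, peaks in no other list also exceeded independence, from 1108 against 0.330 for R339Q to 6987 against 67.6 for H455R.

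Peaks without a counterpart in WT were most numerous in R448Q, with 21528 peaks or 14.8% of its list (14.6 to 15.0), followed by H455R with 20996 (13.1%), R377H with 17761 (12.1%) and R377C with 16326 (10.8%). R342C had 13790, K365T 12480, S354F 12391, Q418R 10451 and R339Q 8638 (7.14%). This order depended on list size and on chromosomes with a shifted share: with lists of equal size R448Q had 25558, R339Q 24146 and H455R 19293, and on chromosomes without shifted segments H455R (9724) had more than R448Q (8098). Few gained peaks were strong: in the strongest 20% of its own list, R448Q had 147 peaks that WT lacks (0.505%), R377H 65, Q418R 34, K365T 25 and R339Q 0. The strongest peaks found in R448Q alone lay 108 kb from Qrfpr (36330663 to 36331000) and 94.0 kb from the sphingosine-1-phosphate receptor gene S1pr1 (115616006 to 115616477), both on chromosome 3. Q418R alone had peaks inside the myosin gene Myo5b (74566510 to 74567028, fold 12.6) and inside Svil (5047951 to 5048280, fold 11.5) on chromosome 18. K365T alone had one 87.5 kb from Ankrd28 on chromosome 14 (31918070 to 31919298, fold 11.8), and H455R alone one 71.9 kb from Smad1, a mediator of BMP signalling, on chromosome 8 (79471323 to 79471582). Chromosome 3 carried a higher share of all peaks in R448Q, as did chromosome 8 in H455R, and on chromosomes without such shifts the R448Q share of strong gained peaks was 0.227%. Limiting the peaks looked for to the stronger 50% of each list left 477 (S354F) to 3193 (R448Q) gained peaks.

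Regions present in all 9 mutant lists and missing from WT numbered 195 of 222457 merged regions. Of these, 34 (17.4%, 95% interval 12.4 to 23.5) lay on chromosome 17 between 70 and 95 Mb, a segment that holds 0.977% of all regions. They include peaks inside Camkmt (85349176 to 85349973), inside Spast, the gene of the microtubule-severing protein spastin (74344522 to 74344945), inside Dync2li1 (84645581 to 84646122), inside Plekhh2 (84619612 to 84620490) and 43.5 kb from Qpct (79133832 to 79134221). Elsewhere they include peaks inside Gatb on chromosome 3 (85637963 to 85638906) and inside Rasa3 on chromosome 8 (13587400 to 13588190). The WT list had 1142 peaks in this segment, where 8 mutant lists predict 1794. H455R was also low there, with 1110 against 1671.

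Sites near gene ends were kept more often than intergenic sites. At equal WT strength, the share of gene-end peaks missing minus that of intergenic peaks was -9.66 points in K365T (16.5% against 26.1%, bootstrap 95% interval -10.7 to -8.67), -9.61 points in R339Q (22.7% against 32.3%) and -6.05 points in H455R (12.1% against 18.1%). The other 6 mutants lay between these values, and every interval excluded 0. Among the strongest 20% of WT peaks, 24.4% were gene-end peaks, but among those missing from a mutant the share was 1.43% (Q418R) to 7.69% (R377C). In R377C, 82.1% of the 39 strong missing sites were intergenic. Gained peaks were gene-end peaks in 5.33% (H455R) to 6.63% (S354F) of cases, against 12.8% of all WT peaks and 10.8% of the weakest 20% of WT peaks. The shares of gained peaks and of strong missing sites were not matched on strength.

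Genes that define the naive pluripotent state kept accessible ends in all mutants. Of 20 genes on that list, 19 had a gene-end peak in WT, and all 19, including Pou5f1, Nanog, Sox2, Esrrb and Zfp42, had one in each of the 9 mutants. Random lists matched on strength lost a median of 14 gene-by-mutant pairs (95% range 2 to 30), which puts this list at the 0.3rd percentile. Dppa3, the remaining member, had a gene-end peak in R377H only. Of the 12 chromatin remodeller genes, among them Smarca4 and Chd4, none lost a gene-end peak in any mutant, but matched random lists also lost a median of 0. Formative and primed pluripotency genes showed 1 missing pair of 72 (Otx2 in K365T), where the WT peak was in fact overlapped and only its edge lay outside the window. Missing pairs were 2 of 99 for mesoderm genes (Evx1 in R377H and Q418R), 2 of 99 for neural genes (Pax6 in K365T and Q418R) and 4 of 54 for primitive endoderm genes (Hnf4a in R377H and Q418R, and Sox17 in R339Q and R342C, again with the WT peak overlapped). Trophoblast genes missed 9 of 72 pairs, with Elf5 in 6 mutants, Krt7 in 2 and Tfap2c in R339Q. Markers of fibroblasts, a possible other cell type, missed 8 of 63 (Dcn in 7 mutants, Prrx1 in R339Q), the 87.4th percentile. Of 9 genes of the two-cell-like state, 0 had a gene-end peak in any list, and 0 peaks lay anywhere in these genes. Whether reads could be placed in them was not examined, so this does not show that they were closed.

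Hox genes and clustered protocadherins, both in arrays rich in CTCF sites, differed in single members. Hox genes missed 25 of 315 pairs, the 51.0th percentile of matched lists. Hoxd11 was without a gene-end peak in all 9 mutants and Hoxd4 in 6, while for Hoxc12 (R342C, K365T and R377C) and Hoxa3 (R339Q and R377H) the WT peak was overlapped and only its edge lay outside the window. Protocadherins missed 37 of 297 pairs (matched median 22, range 6 to 41), with Pcdhac1 missing in R339Q, S354F and Q418R and Pcdhb11 in all 9. Several protocadherin genes share an annotated end, so these counts are not independent. The WT gene-end peak of Pcdhb11 was weak (fold 2.87, the 11th percentile of WT strength). Imprinted genes missed 8 of 198 pairs: Peg3, Usp29 and Peg10 in Q418R, Dlk1 in R339Q and R342C, and Mirg in R339Q, S354F and Q418R. In the CTCF and cohesin list only the cohesin subunit gene Rad21 was affected, missing in 8 mutants with H455R the exception. The WT peak concerned (chromosome 15, 51961432 to 51961701) was weak, while the strongest Rad21 peak, 1.47 kb inside the other annotated end (51990995 to 51992071), was found in all 9 mutants. Over all lists, a peak edge alone accounted for 12 of 108 missing pairs. Of 32 listed genes with a missing gene-end peak, 19 kept the strongest WT peak of the gene in all 9 mutants, and 27 of the WT gene-end peaks concerned lay in the weaker 50% of the list. Over all protein-coding genes, 15477 had a gene-end peak in WT, and 398 (R377C) to 826 (R339Q) of these had none in a mutant.

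The imprinted interval from Meg3 to Mirg, a cluster of maternally expressed noncoding RNA genes that includes Rian, was nearly without peaks in S354F. This interval was singled out after its values were seen, as the longest run missing from S354F among the stronger 60% of WT peaks, 8 in a row from 109640585 inside Rian to 109739797 inside Mirg, with weaker peaks skipped. On chromosome 12 between 109539996 and 109750458, WT had 27 peaks and S354F had 4, and 23 of the 27 WT peaks (85.2%) were missing against 8.87 expected at equal strength (simulated 95% range 5 to 13). The other mutants had 11 (R339Q) to 24 (H455R) peaks there and missed 7 to 16, within their simulated ranges. Over the 9 mutants, WT peaks of the interval were missing 117 times against 87.4 expected. Several of the 23 were missing from other mutants too, and those starting at 109589995 and 109605224, among others, from all 9. Only those starting at 109694808, 109706204, 109707298 and 109724216 were missing from S354F alone. Between Dlk1 and Meg3, S354F missed 14 of 17 WT peaks (expected 6.04, range 3 to 10), and in the 100 kb before Dlk1 it missed 6 of 11 (expected 2.34, range 0 to 5). The draws take peaks as independent. Over all windows of 27 consecutive WT peaks, the largest excess of missing peaks was 6.91 standard deviations in S354F, here, and 5.72 (R339Q) to 7.16 (Q418R, chromosome 6) in the other mutants.

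**Figure D2:**
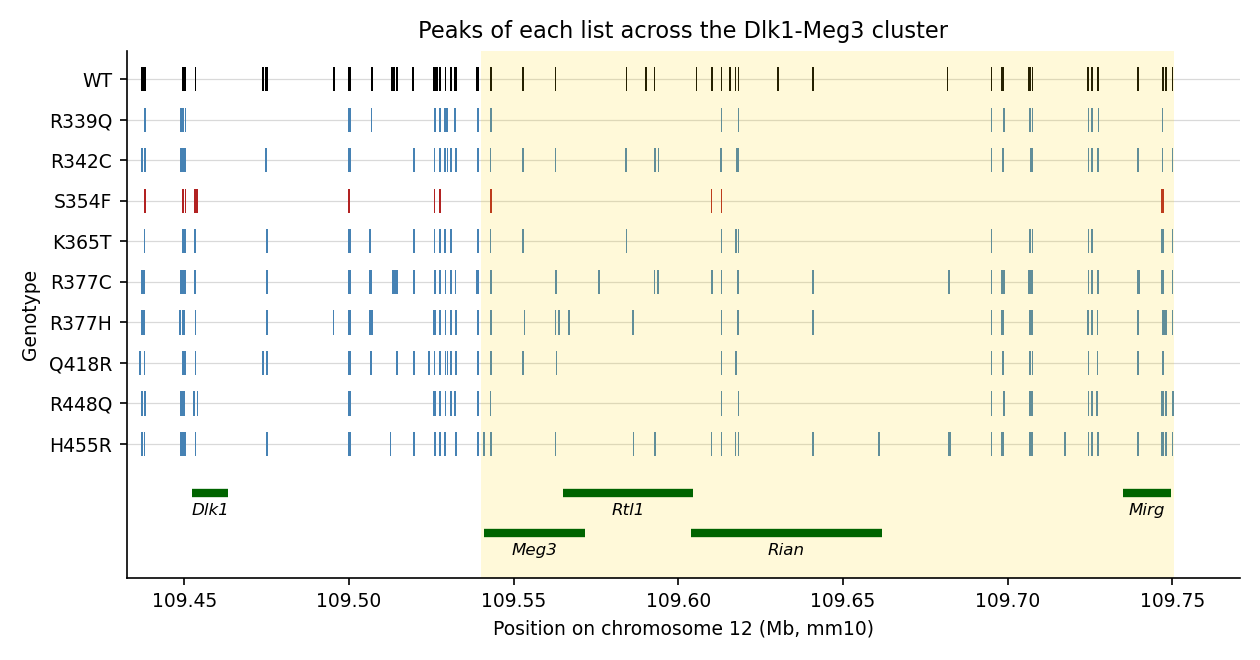
Peaks of each list (boxes, 1 row per genotype, S354F in red) across the Dlk1-Meg3 cluster, with position on chromosome 12 in Mb (mm10) on the horizontal axis, annotated genes in green and the Meg3 to Mirg interval shaded. S354F keeps 4 peaks in the shaded interval, where WT has 27 and the other mutants 11 to 24.

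Substitutions in the same part of CTCF did not give clearly more similar lists. R377C and R377H, 2 substitutions of the same arginine, had a Jaccard index (bp shared over bp covered) of 0.683, rank 5 of the 36 mutant pairs. R339Q and R342C of the third zinc finger reached 0.667 (rank 9), S354F and K365T of the fourth 0.659 (rank 12), and R448Q and H455R of the seventh 0.618 (rank 33). The median of these 4 pairs was 0.663, against 0.651 for the 32 pairs from different parts, which ranged from 0.612 (R339Q and R448Q) to 0.707 (S354F and R377C). WT overlapped most with R377C (0.688) and H455R (0.685) and least with R339Q (0.597). For every pair of mutants, WT peaks were missing from both lists more often than independent losses at equal strength give, by 1.30-fold (R339Q and K365T) to 1.68-fold (S354F and R377C, R377C and H455R). With 4 pairs the difference between same and different parts was not tested.

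**Figure D3:**
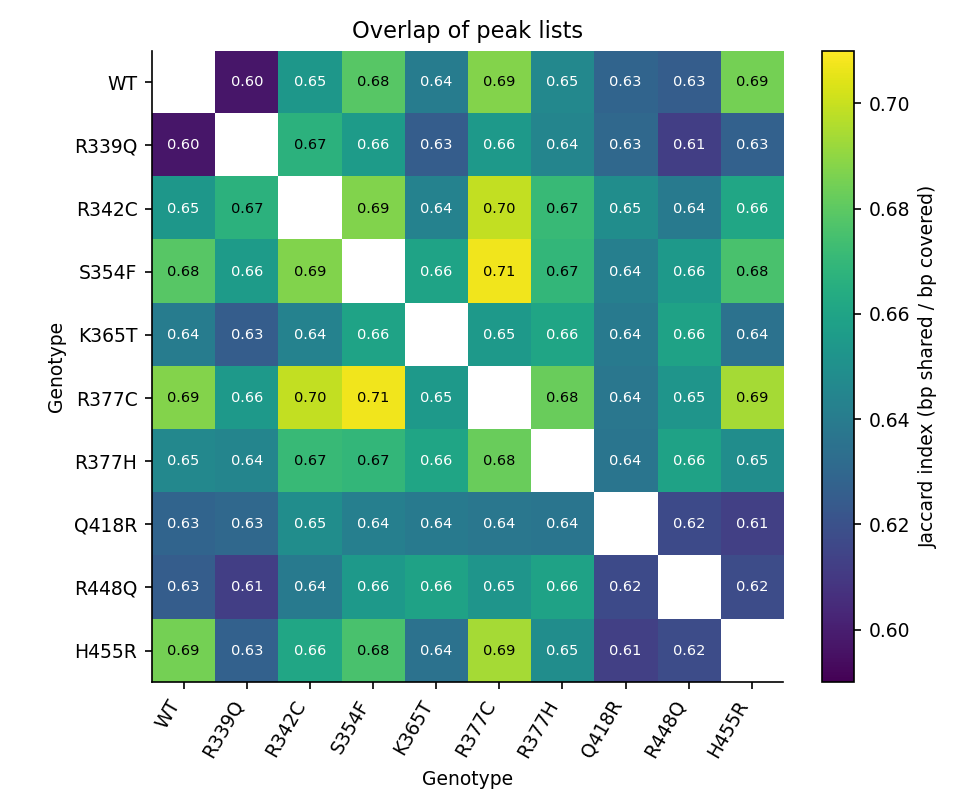
Jaccard index of each pair of peak lists, bp shared over bp covered by either list, as colour and number, with genotypes in order of residue on both axes. The highest value is 0.71 for S354F with R377C and the lowest 0.60 for WT with R339Q.

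List size, a relation examined after the data were seen, went with the share of WT peaks found. Only 7.14% (R339Q) to 14.8% (R448Q) of a mutant list's peaks lacked a WT overlap, so a longer list finds more WT peaks largely by construction. The same holds for covered length, and the p-values of both relations show no separate effect. Over the 9 mutants, the number of peaks and the share found had r = 0.94 (exact permutation p = 0.000474, adjusted 0.00118) and rho = 0.88 (p = 0.00308, adjusted 0.00769), and r = 0.80 (exact p = 0.0359) without R339Q and H455R. Covered length gave r = 0.92 (exact p = 0.000223, adjusted 0.00112) and rho = 0.90. Background coverage itself showed no relation past the threshold with the share found (r = 0.35, exact p = 0.350, adjusted 0.438; rho = 0.55, exact p = 0.133, adjusted 0.166) or with the share of strongest peaks missing (r = 0.29, exact p = 0.451, adjusted 0.451; rho = -0.23, exact p = 0.552, adjusted 0.552). Without R448Q and H455R, r was 0.50 and -0.19. Over all 10 lists, coverage and number of peaks had r = 0.72 (permutation p = 0.0207, adjusted 0.0345) and rho = 0.70 (permutation p = 0.0310, adjusted 0.0517), and without WT and R448Q r was 0.59 over 8 lists (permutation p = 0.122). WT and K365T, whose library codes differ from the rest, were too few to test within a batch, and the batch and the genotype cannot be told apart.

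**Figure D4:**
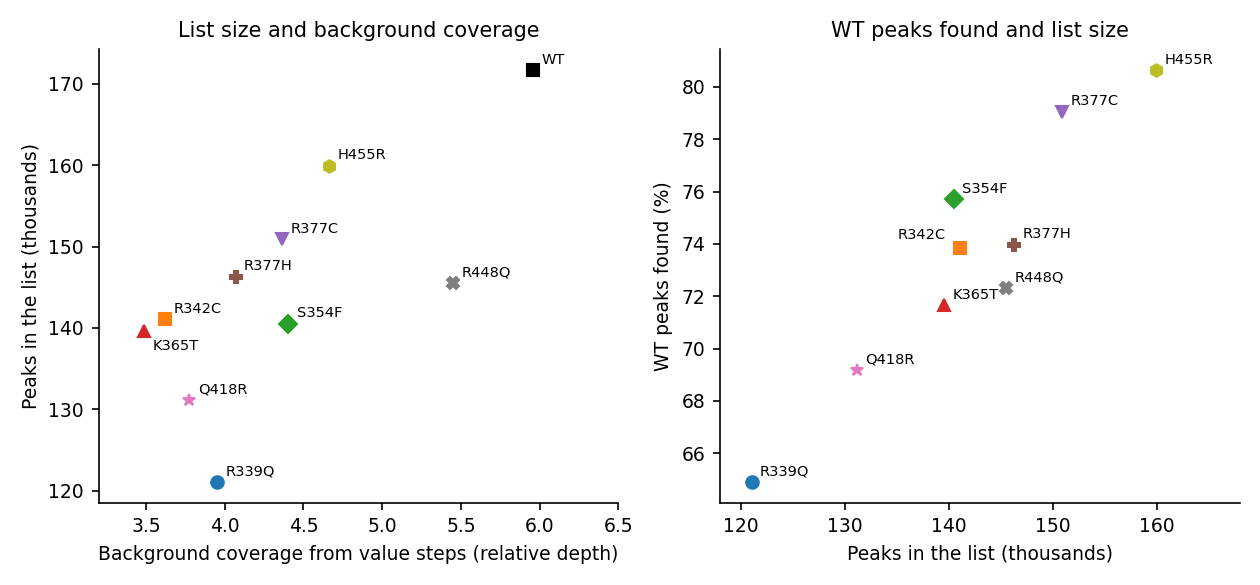
Left, peaks in each list (in units of 1000) against background coverage, a relative depth computed from the steps of the fold values, for the 10 lists; right, share of WT peaks found (percent) against list size for the 9 mutants, 1 labelled point per genotype. R339Q is lowest on both vertical axes, WT highest on the left and H455R highest on the right (80.7%).

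Whole chromosomes differed in their share of peaks, a comparison also made after the data were seen. In R448Q, chromosomes 1, 3 and 8 carried more peaks than the median of the other lists, by 0.31, 0.33 and 0.23 on the log2 scale. Chromosome 8 was higher in H455R (0.26), chromosome 11 in R377H (0.26) and K365T (0.16), and chromosome 1 in K365T (0.22), while chromosome 6 was lower in Q418R (-0.30). Shifted segments also covered 0 to 40 Mb of chromosome 5 in Q418R (0.778 times the median of the other lists), 5 to 45 Mb of chromosome 11 in R448Q (1.26 times), parts of chromosomes 12 and 13 in K365T, and the end of chromosome 17 in WT (0.624 times, from 70 to 95 Mb) and H455R (0.587 times, from 75 to 95 Mb). R339Q, R342C, S354F and R377C had no shifted segment. On the 12 chromosomes without one, the share of WT peaks found was 69.8% in R448Q and 70.0% in K365T.

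**Figure D5:**
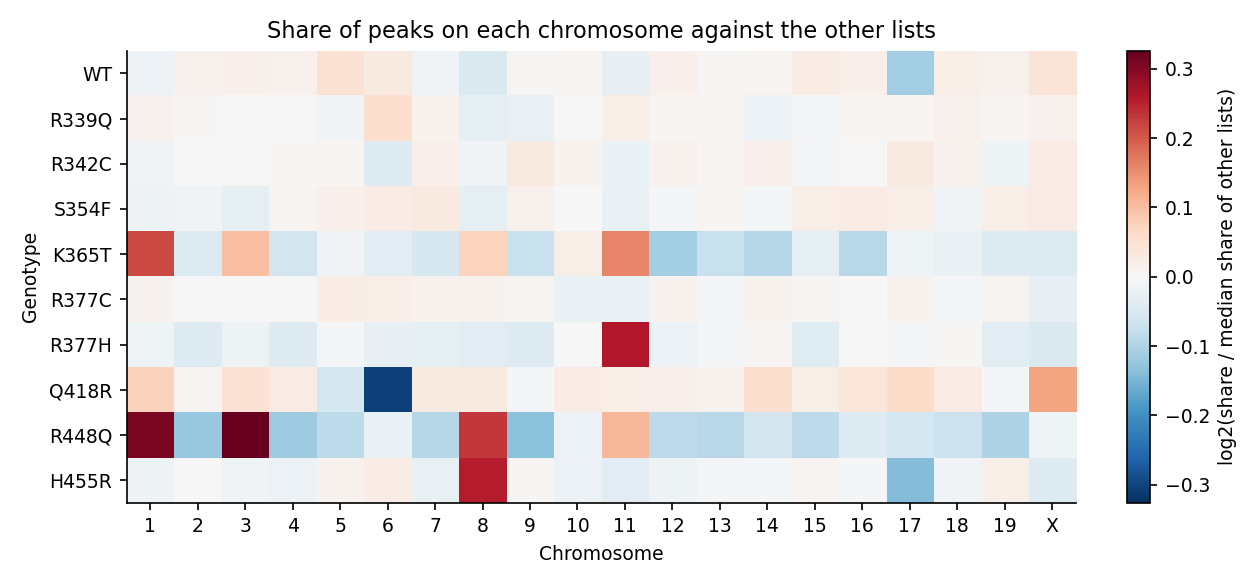
Share of each list's peaks on each chromosome against the median share of the other 9 lists, as log2 colour, with genotypes in rows and chromosomes in columns (Y left out). R448Q stands out on chromosomes 1, 3 and 8, H455R on 8, R377H on 11 and Q418R, lower, on 6.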

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

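The tests in this part on whole chromosomes, on the share of regions in the chromosome 17 segment and on the peaks S354F keeps were chosen after the result was seen; what the rank test of that segment and the window test for S354F would show was written before they were run. A chromosome was singled out when its share of a list's peaks differed from the median of the other lists by at least 0.15 (log2). Chromosome Y, with only 5 (Q418R) to 29 (R448Q) peaks in a mutant list, was left out, although its share differed by more. None of these differences was tested across replicates. The shares singled out were chromosome 1 in K365T (0.22) and R448Q (0.31), chromosome 3 in R448Q (0.33), chromosome 8 in R448Q (0.23) and H455R (0.26), chromosome 11 in K365T (0.16) and R377H (0.26), and chromosome 6 in Q418R (-0.30).

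A local cluster of sites is argued against, since 97.4% of the 232 bins of 5 Mb on the shifted chromosomes lay on the side of the shift (20 of 26 for chromosome 8 in H455R, all bins for the rest). Ranks within each list were compared over the 81151 regions present in all 10 lists. For 8 of 8 shifted chromosomes the mean rank moved by 2.15 to 3.31 percentile points, in the direction of the shift. These changes lay beyond the 95th percentile (1.24) of 192 other pairs of chromosome and list, of which the largest was 2.61. A copy number change in the line, a candidate explanation, needs the ranks to move in that direction. However, the chromosomes were chosen by peak counts of the same lists, and a changed signal changes both counts and folds. The ranks therefore add no independent evidence for copy number, or against depth of the list, which would act on all chromosomes alike. Any other cause that acts on a whole chromosome would move them too. Copy number in the lines was not measured, and an effect of the CTCF substitution on a whole chromosome stays untested, since each line is 1 genotype.

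The regions found in all 9 mutants and not in WT read at first as sites that respond to any CTCF substitution, yet 17.4% of them lay in 1 segment of chromosome 17, and 161 lay outside it. Even the full 195 are fewer than the WT peaks missing from any single mutant list alone (274 in R377C to 3889 in R339Q). WT has the most peaks (171719) and the highest background coverage (5.96), so a low number was likely whatever the genotype. The comparison was not adjusted for list size or depth and cannot show whether WT is set apart, and the reading stays undecided. A lower copy number of the segment in the WT line may account for its low number of WT peaks, for which it was chosen: over its 692 regions present in all 10 lists, the mean rank in WT was -10.6 percentile points from the median of 8 mutant lists, where the lowest of 110 other windows of 25 Mb was -2.28. These ranks come from the same lists whose counts chose the segment, so they are no independent test of copy number. They are relative to 8 mutant lists, so they do not show which side changed. H455R, which carries a mutant CTCF, stood at -9.26 by rank (lowest other window -3.45). Regions such as those in Camkmt and Spast therefore cannot be assigned to the loss of WT CTCF from these lists.

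In S354F the interval from Meg3 to Mirg was chosen for its missing peaks, so 23 missing where 8.87 were expected does not by itself argue against depth or uneven calling. Over all windows of 27 consecutive WT peaks the largest excess in S354F was 6.91 standard deviations. Q418R reached 7.16 on chromosome 6 (where its share of peaks was low) and R448Q 6.69 on chromosome 5, so uneven calling remains a candidate explanation. R339Q, R342C, K365T, R377C, R377H and Q418R had lower background coverage than S354F. They still held 11 (R339Q) to 21 (R377C) peaks in the interval, against 4 in S354F. These numbers argue against depth of the whole list as the only cause in this interval. Loss of both copies of the whole region is argued against by the 4 WT peaks kept. An altered imprint at the Dlk1-Meg3 cluster, known from cultured embryonic stem cells, stays open, because DNA methylation was not analysed here and the 4 peaks cannot decide it. An effect of the S354F protein and an event in that line before induction also stay open with 1 line per genotype.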

How the results depend on the processing

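Leaving out chromosomes with shifted segments, giving losses a share per chromosome, and the relation of depth to the share of WT peaks found, with its alternatives, were chosen after the data were seen. The rest were planned, though the gene-end minus intergenic difference at equal strength to which some apply was not in the plan. No paired analysis was possible because each list combines both replicates, so neither a replicate block nor leaving out a replicate could be run. The alternatives on the CTCF motif (threshold, search window, width, distal peaks, GC content, list size against motif retention) were not run without a genome sequence. Of 127 alternative values, 47 stayed within their error or within 1.5 times the count, 78 moved beyond it, 2 passed the threshold that the original value missed, and 0 changed direction. Most of these values are counts or shares without a sign, which cannot change direction, and changes in the order of mutants were not counted. The values that moved follow.

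With at least 50% of the tested peak covered, the share of WT peaks found was 60.2% for R339Q, 70.5% for R342C, 73.0% for S354F, 67.6% for K365T, 76.6% for R377C, 70.5% for R377H, 65.1% for Q418R, 69.0% for R448Q and 78.1% for H455R. With the stronger 50% of WT peaks looked for, it was 89.2% for R339Q, 94.5% for R342C, 94.8% for S354F, 93.8% for K365T, 96.4% for R377C, 94.2% for R377H, 92.2% for Q418R, 91.9% for R448Q and 96.8% for H455R. With lists of equal size it was 78.4% for R339Q, 82.5% for R342C, 84.0% for S354F, 81.5% for K365T, 84.4% for R377C, 81.0% for R377H, 81.1% for Q418R, 78.6% for R448Q and 83.8% for H455R. On chromosomes without shifted segments it was 70.0% for K365T, 73.1% for R377H, 69.9% for Q418R, 69.8% for R448Q and 80.3% for H455R.

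Gained peaks among the stronger 50% of each list numbered 486 in R339Q, 835 in R342C, 477 in S354F, 1154 in K365T, 924 in R377C, 1732 in R377H, 964 in Q418R, 3193 in R448Q and 1483 in H455R. With equal sizes they numbered 24146 in R339Q, 19744 in S354F, 19637 in K365T and 20870 in Q418R, since WT then loses its weaker peaks. On chromosomes without shifted segments, which are fewer, they numbered 3999 in R339Q, 6709 in R342C, 5962 in S354F, 4902 in K365T, 7759 in R377C, 7749 in R377H, 5151 in Q418R, 8098 in R448Q and 9724 in H455R.

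With 2.5 kb around gene ends, the gene-end minus intergenic loss was -7.45 points in R339Q, -6.58 in R342C, -7.41 in S354F, -7.99 in K365T, -6.41 in R377C, -5.70 in R377H, -6.63 in Q418R, -5.78 in R448Q and -4.93 in H455R. Listed genes without a gene-end peak in the mutant then numbered 15 in R342C and 10 in R448Q, and with 0.5 kb 5 in R342C, 9 in K365T and 5 in R377C. For these counts and differences the cause was not tested beyond the wider or narrower window.

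WT peaks in no mutant list numbered 204 among the stronger 50% of WT (0.00700 expected), 3029 with equal sizes (59.3 expected) and 4879 on chromosomes without shifted segments (169 expected). With a mutant as the reference the number was 1108 for R339Q, 2440 for R342C, 2138 for S354F, 2396 for K365T, 2617 for R377C, 3836 for R377H and 2913 for Q418R. The rank correlation with the share of WT peaks found was 0.883 for number of peaks (exact p = 0.00308) and 0.900 for covered length (exact p = 0.00203), against 0.55 for background coverage. The relations with number of peaks and covered length are largely built in, since most peaks of each mutant list overlap WT. What depth limits was not separated from genotype: of the weakest 20% of WT peaks, R448Q, with the highest coverage of the mutants (5.45), missed 56.3%, and H455R (4.66) 46.5%.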

Other observations

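The region tests in this part were chosen after the data were seen, on gene clusters from the lists fixed earlier, and none is a test across replicates. Accessible sites of the Hoxa and Hoxb clusters were kept more often in some mutants than sites of equal strength elsewhere. Across the 9 mutants, WT peaks of the Hoxa cluster (chromosome 6, 52154367 to 52261880, 32 WT peaks) were missing 54 times where 109 were expected, 0.496 times, and in 7 mutants the number lay below the simulated 95% range. R448Q missed 3 of these 32 peaks (expected 12.1, range 7 to 17) and S354F 4 (expected 11.1, range 7 to 16). The Hoxb cluster (chromosome 11, 96193316 to 96369254, 39 WT peaks) gave 59 against 103, with 4 mutants below the range. The draws were not matched on chromosome, and 2 of these 4 mutants, K365T and R448Q, missed fewer WT peaks on the whole of chromosome 11 (21.8% and 22.8%) than on all chromosomes (28.3% and 27.7%). The Hoxc cluster gave 64 against 89.2 and the Hoxd cluster 44 against 67.0, each with 1 mutant below the range. Part of this follows from their many gene-end peaks: drawn from peaks of equal strength and the same location class, 94.1 were expected for Hoxa (3 mutants below) and 90.6 for Hoxb (2 below), and 80.4 for Hoxc and 61.7 for Hoxd (0 below in each).

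The protocadherin array on chromosome 18 (36929285 to 37842873, 90 WT peaks) missed 197 against 234 expected, with R448Q at 12 of 90 (expected 27.2, range 20 to 35) and R339Q at 42 (expected 34.5, range 27 to 43). With the location class matched, 206 were expected, and R339Q lay above its range (31.0 expected, 24 to 38). Of the imprinted clusters other than Meg3 to Mirg, none lay outside its range at equal strength in any mutant: H19 to Igf2 gave 16 against 16.2, Peg3 with Usp29 31 against 48.7, Gnas 43 against 53.7 and Igf2r with Airn 37 against 43.0. These clusters hold few WT peaks, from 5 in H19 to Igf2 to 20 in Gnas. Where a range starts at 0, as for H19 to Igf2 in all mutants but R339Q, no number can lie below it. The check therefore had little power to show a change there. Over these 12 regions and 9 mutants, 16 of 108 numbers lay below and 0 above their ranges, where at most 5.4 in all would fall outside by chance if peaks were independent. With the location class also matched, 6 lay below and 1, R339Q at the protocadherins, above.

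Runs of missing peaks were counted among the stronger 60% of WT peaks, skipping weaker peaks between them, and apart from S354F the longest run of each mutant was no longer than the longest of its draws. S354F, R342C and R377C shared a run of 6 peaks missing inside Poc1b on chromosome 10 (99179240 to 99197440). R342C, R377C and R377H shared a run of 6 at Magea4 and Gabre on chromosome X (72218201 to 72256963). K365T missed 8 of these stronger peaks in a row across an olfactory receptor cluster on chromosome 2 (111326377 to 112001505), and the longest run in 100 draws for that list was also 8. For S354F, from Rian to Mirg, it was 8, against 6 as the longest in 100 draws.

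The K365T list, which like WT combines library codes far apart, was not closer to WT than the others: its Jaccard index with WT was 0.640, against a median of 0.646 over the mutants.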
